A study of Mus musculus with 17 samples.

How the data were processed

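Messenger RNA was sequenced from glomeruli-enriched kidney cortex of 17 mice of the BTBR strain. Per the labels, the ob/ob mice carry the ob mutation of the leptin gene Lep, which removes leptin and leads to obesity and diabetes on this strain background. Per the labels' protocols, 5 of them were given saline and 7 were given atrasentan, an antagonist of the endothelin A receptor, at 5 mg per kg per day in the drinking water, from 18 weeks to 24 weeks of age. The 5 wild type BTBR mice were killed at the same age and are the untreated, lean controls. RNA was taken from total RNA by poly(A) selection, made into TruSeq libraries with a kit that does not mark the strand, and sequenced single-end on an Illumina HiSeq, per the labels' protocols. Each library is a separate mouse, so the errors given here are between animals.

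The authors deposited a table of raw read counts for 53379 genes and all 17 libraries. The submitters' processing notes list STAR, HTSeq, DESeq2, edgeR and limma and the genome build GRCm38, with no versions and no roles. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an antisense gene that overlaps it cannot be told apart. The count table ends in 5 HTSeq lines that name no gene. They hold reads that aligned to several places (23.4% to 31.8% of the reads in a library), reads outside genes (3.17% to 8.58%) and reads that fell on more than 1 gene (2.93% to 3.37%). These lines were kept out of the library sizes and the tests. Reads with several alignments were not assigned to genes, so values of genes with near-identical copies (H2-D1, Hba-a1, C4b, Cyp2a5, Serpina3f, Gbp8, Nat8f5 and Ugt2b34 among those named) are uncertain. The authors also deposited a table of normalized values on a log2 scale for 17338 genes. The transform behind it and the filter on its genes are not given in the sources used here, and 5 of its genes have no read in the 17 libraries. This table was used for 1 alternative only. Gene symbols came from the GENCODE annotation of GRCm38 (release M21), which gave a symbol for 53274 gene IDs (99.8%); 50604 IDs matched with their version. Coordinates are 1-based and from that annotation.

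Gene reads per library ran from 29161833 to 52528747. Of the genes in the table, 33758 had at least 1 read. The libraries of a group were compared with each other in all 41 pairs by a chi-square test of their counts. The chi-square per degree of freedom was between 27.0 and 279.6, so no pair was a repeat of 1 library and each was counted once. The labels give the same batch for all libraries and number no replicates. Replicate numbers here follow the order of the deposited samples, only name a library, and pair nothing. The genotype labels differ between the groups ('BTBR ob' with atrasentan, 'ob/ob-d30' with saline and 'WT-d30' in wild type), and what the added part stands for is not given in the sources used here. In the labels the library numbers follow the groups, so an effect of the order of preparation and an effect of the group cannot be told apart. Counts on 4 Y-linked genes (at most 7 reads in a library) and on Xist (20.7 to 72.9 CPM) were female-type in all 17 libraries, so the planned fit with sex as a covariate was not run.

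Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (glmQLFit and glmQLFTest) on the deposited counts. Low-count genes were removed with filterByExpr by group, which left 17766 genes. Library sizes were scaled with TMM factors between 0.892 and 1.15, and all 17 libraries entered 1 fit with a shared estimate of the spread (biological coefficient of variation 0.312). The adjusted p is the Benjamini-Hochberg value over all genes tested in a comparison, a gene was called changed at an adjusted p under 0.05 with no minimum fold, and all tests are two-sided. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM, computed with the TMM-scaled library sizes, and means of gene lists are means of log2 CPM with a prior count of 2.

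In all, 34 gene lists (731 symbols, of which 691 were distinct and 683 were found) were written before the data were examined, as were the designs, the tests, the rule for named genes and most alternatives. They cover cell types of the kidney cortex, pathways and technical measures. The technical lists are those of immediate early and heat shock, circadian clock, mitochondrially encoded and cytosolic ribosomal protein genes. Lists were tested with camera (limma 3.58.1) with its preset correlation of 0.01 between genes, and the p-values were adjusted over the 34 lists. Camera asks whether a list moved relative to the other genes. Each list was also tested with the correlation estimated from these libraries and with fry, which asks whether the genes of a list move, on balance, one way. With the estimated correlation no list passed in any comparison, and the lowest adjusted p was 0.392 for saline against wild type, 0.336 for atrasentan against saline and 0.564 for atrasentan against wild type. The number of list members called is given over all genes tested and adjusted over the list alone. Measures with 1 value per library were compared with exact permutation tests of the group means, which cannot give a p under 0.00794 for 5 against 5 mice or 0.00126 for 7 against 5, and were adjusted over the 3 comparisons.

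The genes named in each comparison came from a fixed rule. It takes Clu, the 3 endothelin genes Edn1, Ednra and Ednrb, and the 6 largest rises and 6 largest falls among genes with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the libraries of the groups, without predicted genes. It also takes up to 4 members with the smallest p from each list described, and up to 6 genes called in both disease and treatment in each direction. The text names part of the genes from the lists, and that choice was made with their values in view. The lists were tested whole, and 2 of their genes are not reported here.

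The alternatives tried were DESeq2 1.42.0, limma-voom, 2 other scalings (RLE and upper quartile), no low-count filter, a fit of the 2 groups compared alone, a minimum fold of 1.5, the glomerular share of each library as a covariate, and leaving out each library in turn. For the gene lists the estimated correlation and fry were added to these, and for the overlap of disease and treatment a split of the saline libraries. After the data were seen, 5 more were added: the mean of the proximal tubule list as a covariate, the share of reads outside genes as a covariate, leaving out saline libraries 1 and 3 together, leaving out atrasentan libraries 2 and 5 together, and limma on the deposited normalized values.

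The fits were tested on simulated counts drawn from the means and sizes of the real libraries with 200 changed genes. For saline against wild type, edgeR found 98.5% of genes changed 4-fold, 68.7% of those changed 2-fold and 35.8% of those changed 1.5-fold. For atrasentan against saline these shares were 92.4%, 68.7% and 32.8%, and for atrasentan against wild type 97.0%, 62.7% and 35.8%. With edgeR 7, 7 and 10 unchanged genes were called in the 3 simulations, and with DESeq2 35, 42 and 34.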

Results

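RNA was counted in glomeruli-enriched kidney cortex of 5 wild type BTBR mice, 5 BTBR ob/ob mice given saline and 7 BTBR ob/ob mice given atrasentan. The comparisons ask what differs in the diabetic ob/ob kidney, what differs after 6 weeks of endothelin A receptor blockade, and how treated mice compare with wild type mice. The title of the series is about clusterin, the secreted chaperone encoded by Clu. Gene reads per library ran from 29161833 to 40965108 in wild type, from 35938445 to 40268662 with saline and from 37252939 to 52528747 with atrasentan. Of 17766 genes tested with edgeR, 910 were called changed in saline-treated ob/ob against wild type mice. With atrasentan 6001 were called against saline and 5190 against wild type. The first principal component of log2 CPM held 39.8% of the variance and the second 14.1%.

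The atrasentan libraries stood apart from the others in 2 library measures. A mean of 22142 ± 624 genes (SD, n = 7) had at least 1 read with atrasentan, against 24739 ± 370 with saline (n = 5) and 24504 ± 396 in wild type (n = 5). The share of reads outside genes was 3.97% ± 0.849 with atrasentan, 7.34% ± 0.828 with saline and 7.85% ± 0.946 in wild type. In both measures every atrasentan library lay below every other library (exact permutation p = 0.00126 against each group, adjusted p = 0.00189). That p is the smallest that 7 against 5 mice can give. Saline and wild type libraries did not differ detectably in genes detected (exact p = 0.365) or in reads outside genes (exact p = 0.397). Mitochondrially encoded genes took 0.598% ± 0.219 of gene reads with atrasentan, 1.01% ± 0.342 with saline and 0.662% ± 0.129 in wild type. The difference between atrasentan and saline had an adjusted exact p of 0.0985. The share of the 10 most abundant genes was 5.76% ± 0.282 with atrasentan, 6.08% ± 0.920 with saline and 4.55% ± 0.342 in wild type.

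**Figure D1:**
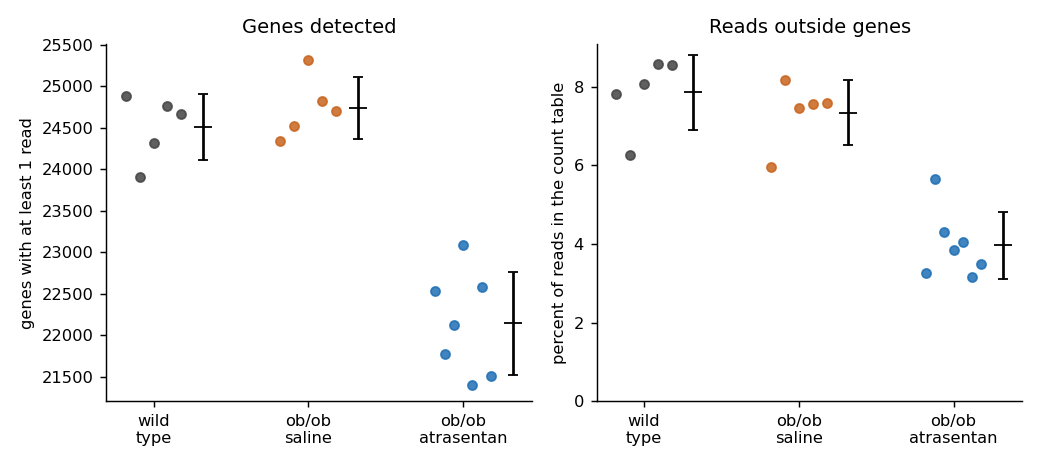
Genes with at least 1 read (left) and reads outside genes as a percent of the reads in the count table (right), 1 point per library in 3 groups, with mean and SD beside the points. Atrasentan libraries lie below the others in both, with means of 22142 genes and 3.97% of reads.

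Markers of podocytes and of proximal tubule stood in different proportion in the groups. The mean log2 CPM of podocyte markers minus that of proximal tubule markers, called the glomerular share here although it also falls if podocytes express less of their markers, was 0.50 ± 1.27 with saline, 2.63 ± 0.57 in wild type and 2.68 ± 0.98 with atrasentan (SD, n = 5, 5 and 7). It was lower with saline than in wild type by a difference of -2.13 (exact permutation p = 0.0238, adjusted p = 0.0357) and higher with atrasentan than with saline by 2.18 (exact p = 0.00884, adjusted p = 0.0265). Atrasentan and wild type differed by 0.06 (exact p = 0.909). With glomerular endothelium markers in place of podocyte markers, the difference of saline from wild type was -1.36 (adjusted exact p = 0.0635) and that of atrasentan from wild type was 1.92 (adjusted exact p = 0.0114). The proximal tubule list mean spread from 5.63 to 7.95 over the saline libraries, and saline libraries 1 (7.82) and 3 (7.95) held the most. Of the 22 proximal tubule markers 3 are also in another list, as are 1 of the 26 podocyte markers, 5 of the 20 macrophage markers, 1 of the 20 glomerular endothelium markers and 4 of the 21 mesangium markers.

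**Figure D2:**
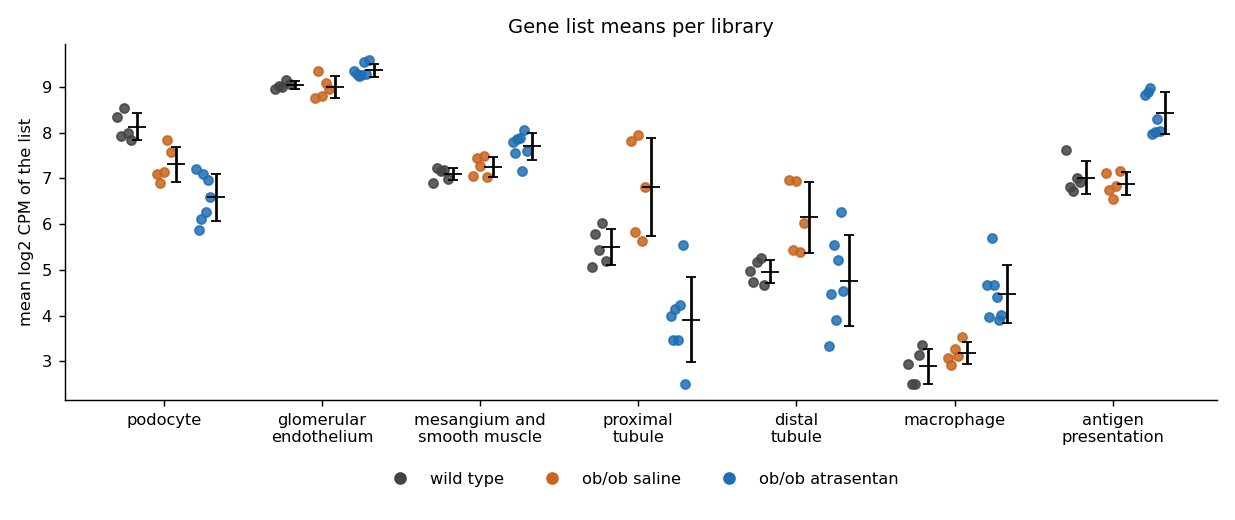
Mean log2 CPM of the genes of 7 lists in each library, 1 point per library, with group mean and SD. The proximal tubule mean is 6.81 with saline, 5.50 in wild type and 3.91 with atrasentan, and the podocyte mean falls from 8.13 in wild type to 7.31 and 6.59.

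In saline-treated ob/ob mice against wild type mice, markers of podocytes, the cells that wrap the glomerular capillaries, were lower and markers of tubule segments were higher. Of 25 podocyte genes, 10 fell and 15 did not pass, and none rose. Adjusted over the list alone 17 fell. Plce1, a phospholipase whose loss causes nephrotic syndrome, fell by 1.38 ± 0.28 on the log2 scale (SE, 38.9 ± 8.33 against 101 ± 11.8 CPM, mean ± SD, n = 5 each). The podocyte transcription factor Lmx1b fell by 1.35 ± 0.31, Thsd7a, a podocyte membrane protein, fell by 1.01 ± 0.22, and Nes, the intermediate filament nestin, fell by 0.64 ± 0.12 (edgeR adjusted p of at most 0.0222 for all 4). The list median was -0.94 (camera adjusted p = 7.83e-16), and with an estimated correlation the adjusted p = 0.392. Of 22 proximal tubule genes, 8 rose, 1 fell and 13 did not pass, and adjusted over the list alone 20 rose and 2 fell (list median 1.92, camera adjusted p = 1.09e-09, and adjusted p = 0.392 with an estimated correlation). Fbp1, an enzyme of gluconeogenesis, rose by 2.33 ± 0.54, the transcription factor Hnf4a by 2.21 ± 0.55, the lactate transporter Slc5a12 by 2.11 ± 0.52 and the glucose transporter Slc5a2 (SGLT2) by 1.98 ± 0.49 (adjusted p = 0.0242, 0.0317, 0.0297 and 0.0306).

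Markers of later tubule segments were also higher in the saline group. Of 12 distal tubule genes 4 rose, both over all genes and adjusted over the list alone, with a median of 1.34 (camera adjusted p = 0.000179, and adjusted p = 0.392 with an estimated correlation). Of 13 collecting duct genes 2 rose, and 8 rose adjusted over the list alone, with a median of 1.78 (camera adjusted p = 8.37e-06, and adjusted p = 0.392 with an estimated correlation). The calcium-binding proteins Calb1 and S100g rose by 2.30 ± 0.62 and 2.59 ± 0.72, the proton pump subunit Atp6v0d2 by 2.35 ± 0.65 and the chloride-bicarbonate exchanger Slc4a1 by 2.24 ± 0.63 (edgeR adjusted p between 0.0420 and 0.0488). None of 12 loop of Henle genes was called (median 0.46, camera adjusted p = 0.383). With the glomerular share as a covariate that list turned to -1.52 and passed (adjusted p = 1.02e-09). In the other glomerular lists edgeR called 1 of 20 endothelial genes and no mesangial gene of 20. The endothelial list had a median of 0.01, which is negative (-0.07) with upper-quartile scaling, a mean of -0.03 and a test direction of down (camera adjusted p = 0.383), and the mesangial median was 0.20 (camera adjusted p = 0.452). The endothelial list passed without saline library 2 (-0.07, adjusted p = 0.0299). The mesangial list passed with the glomerular share as a covariate (0.17, adjusted p = 0.0206). The endothelial gene called was Cldn5, a tight junction protein that podocytes also express, which fell by 1.16 ± 0.18 (adjusted p = 0.00344). None of 20 macrophage genes was called, and here the list median was -0.08 while the mean was 0.25 and the test direction up (camera adjusted p = 0.383). The complement subunit C1qa stood at 5.40 ± 2.52 CPM against 1.58 ± 0.829 (log2 fold change 1.76 ± 0.65, adjusted p = 0.116). C1qa passed without atrasentan library 3 (1.76, adjusted p = 0.0307) and in the fit of the 2 groups alone (1.74, adjusted p = 0.0326). Of 18 lymphocyte genes 1 fell, and 5 fell adjusted over the list alone (median -0.60, camera adjusted p = 1.47e-05, and adjusted p = 0.392 with an estimated correlation).

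Metabolic and oxidative stress lists were higher with saline than in wild type, in the libraries that also held more proximal tubule RNA. Of 28 genes of fatty acid oxidation in peroxisomes and mitochondria, 5 rose and none fell, with 19 rising adjusted over the list alone (median 0.70, camera adjusted p = 4.09e-09). Ppara, the transcription factor that drives the pathway, rose by 1.97 ± 0.51 (edgeR adjusted p = 0.0365). Of 28 glucose handling genes 7 rose, and 17 rose and 2 fell adjusted over the list alone (median 0.52, camera adjusted p = 4.84e-07), among them the glucose transporter Slc2a2 (2.51 ± 0.55, adjusted p = 0.0205). Of 23 targets of the antioxidant regulator NRF2, 8 rose, and 16 rose adjusted over the list alone (median 0.58, camera adjusted p = 3.26e-08). Osgin1 rose by 1.93 ± 0.37, the glutathione peroxidase Gpx1 by 1.18 ± 0.26 and the catalase gene Cat by 1.10 ± 0.25. For these 3 lists the adjusted p = 0.392 with an estimated correlation. No oxidative phosphorylation gene of 38 was called by edgeR over all genes, and 12 rose adjusted over the list alone (median 0.35, camera adjusted p = 1.29e-05, and adjusted p = 0.637 with an estimated correlation). Of 24 complement genes 4 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell (median 0.43, camera adjusted p = 0.0101, and adjusted p = 0.488 with an estimated correlation). The central component C3 rose from 14.3 ± 2.13 to 77.8 ± 48.8 CPM (2.44 ± 0.47, adjusted p = 0.0113), and C4b, C2 and Cfb rose by 2.45 ± 0.54, 1.70 ± 0.42 and 1.44 ± 0.34. Of 13 renin-angiotensin genes 4 rose, over all genes and adjusted over the list alone (median 0.18, camera adjusted p = 0.0571), among them angiotensinogen, Agt (3.21 ± 0.65). Matrix genes went both ways. Of 43 there, 2 rose and 2 fell, with 4 and 2 adjusted over the list alone, and the list median of 0.07 turned to -0.01 with upper-quartile scaling (camera adjusted p = 0.571) and passed with the glomerular share as a covariate (0.14, adjusted p = 0.00638). The basement membrane collagen Col8a1 rose by 0.82 ± 0.19 and the protease inhibitor Timp3 by 0.74 ± 0.18, while the fibrillar collagen Col1a2 fell by 1.15 ± 0.20.

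By size of change, the largest rises without overlap between the groups were those of Qrfpr, a neuropeptide receptor (4.44 ± 0.62, adjusted p = 0.00224), Nat8f5 (4.18 ± 0.87), the sugar transporter Slc5a10 (3.83 ± 0.81), Cyp2a5 (3.52 ± 0.94) and Cyp2e1 (3.33 ± 0.86), both cytochrome P450 enzymes. Next came Mogat2, an acyltransferase of triglyceride synthesis (3.28 ± 0.77). The largest falls were those of Brinp2 (-2.66 ± 0.60), the potassium channel subunit Kcnj8 (-2.39 ± 0.45), the matrix protein periostin, Postn (-2.27 ± 0.31, adjusted p = 0.00192), the connexin Gja3 (-2.02 ± 0.32), the prostaglandin E receptor Ptger2 (-1.91 ± 0.31) and Sobp (-1.79 ± 0.33). The clock transcription factor Arntl fell by 2.69 ± 0.58 (adjusted p = 0.0191), with 31.5 ± 26.4 CPM in wild type, and E-selectin, Sele, rose by 1.43 ± 0.33 (adjusted p = 0.0251).

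Over all genes, 570 rose and 340 fell (edgeR, adjusted p under 0.05), which became 503 and 483 with upper-quartile scaling and 267 and 283 with limma-voom. In all 2003 were called with DESeq2 and 1430 in the fit of the 2 groups alone. An unadjusted p under 0.05 was reached by 3825 genes. The count depended on single libraries and on the covariates made from tubule markers. It was 6 with the glomerular share as a covariate, 91 with the proximal tubule mean as a covariate, 409 with the share of reads outside genes as a covariate and 54 without saline libraries 1 and 3. It was 331, 319, 280, 543 and 220 without wild type library 1, 2, 3, 4 or 5, and 226, 216, 1523 and 594 without saline library 1, 3, 4 or 5. Of 52 genes named here and called in this comparison, 27 lost the call when some single library was left out. The calls lost were 19, 19, 22, 8 and 24 without wild type library 1, 2, 3, 4 or 5, 22, 25 and 7 without saline library 1, 3 or 5, and at most 3 without any atrasentan library. Without saline libraries 1 and 3 together 43 of the 52 were lost. The highest adjusted p of any of the 27 with 1 library left out was 0.146, for Slc4a1 without saline library 1. With the glomerular share as a covariate the lymphocyte, complement and NRF2 lists lost their calls (adjusted p = 0.433, 0.119 and 0.126), and the medians of the proximal tubule, distal tubule, collecting duct and fatty acid oxidation lists turned to -0.06, -0.17, -0.42 and -0.04.

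In atrasentan-treated against saline-treated ob/ob mice, proximal tubule markers fell and antigen presentation, interferon response and macrophage genes rose. Of 22 proximal tubule genes 20 fell and none rose, over all genes and adjusted over the list alone (list median -3.02, camera adjusted p = 6.50e-16, and adjusted p = 0.470 with an estimated correlation). Slc5a12 fell by 4.16 ± 0.49 on the log2 scale (SE, 7.44 ± 4.21 CPM, n = 7, against 133 ± 91.8, n = 5), Slc5a2 by 3.79 ± 0.46, Keg1 by 3.43 ± 0.46 and Gatm, an enzyme of creatine synthesis, by 2.95 ± 0.34 (edgeR adjusted p between 9.05e-05 and 0.000172). Among later segments 6 of 12 loop of Henle genes fell, among them the sodium-potassium-chloride transporter Slc12a1 (-1.78 ± 0.60, adjusted p = 0.0310). So did 4 of 12 distal tubule genes, among them Calb1 (-1.67 ± 0.54, adjusted p = 0.0258), and 3 of 13 collecting duct genes, among them Slc4a1 (-1.96 ± 0.56, adjusted p = 0.0130). Adjusted over the list alone 7, 6 and 1 fell. The medians were -1.49, -1.09 and -1.13 (camera adjusted p = 0.00359, 0.0149 and 0.0634), and the adjusted p = 0.566 with an estimated correlation for loop and distal tubule. Without saline libraries 1 and 3 the loop and distal tubule lists did not pass (-0.68 and -0.32, adjusted p = 0.0807 and 0.219). With the glomerular share as a covariate their medians turned to 0.046 and 0.23 (camera adjusted p = 0.634 and 0.829). The collecting duct list passed without saline library 4 (-1.30, adjusted p = 0.0328) or atrasentan library 2 (-1.15, adjusted p = 0.0227), 5 (-1.45, adjusted p = 0.0202) or 6 (-1.17, adjusted p = 0.0339). It also passed without atrasentan libraries 2 and 5 together (-1.97, adjusted p = 0.00444) and without the low-count filter (-1.03, adjusted p = 0.0299), and its median was 0.80 with the glomerular share as a covariate (adjusted p = 0.155).

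Within the glomerular markers, podocyte genes were lower with atrasentan while endothelial and mesangial genes were higher. Of 25 podocyte genes 10 fell and 1 rose, with 11 and 1 adjusted over the list alone (median -0.55, camera adjusted p = 0.00197, and adjusted p = 0.583 with an estimated correlation). The slit diaphragm scaffold Magi2 fell by 1.74 ± 0.25, the basement membrane ligand Npnt by 1.36 ± 0.30 and Plce1 by 1.03 ± 0.25 (edgeR adjusted p = 0.000221, 0.00291 and 0.00489). Of 20 glomerular endothelium genes 11 rose, and 13 rose adjusted over the list alone (median 0.37, camera adjusted p = 8.48e-05, and adjusted p = 0.470 with an estimated correlation). The adhesion molecules Icam2 and Esam rose by 0.72 ± 0.15 and 0.67 ± 0.18, the endothelial receptor kinase Tie1 by 0.48 ± 0.13 and Ehd3, a protein of glomerular endothelial membranes, by 0.48 ± 0.12. Of 20 mesangium and vascular smooth muscle genes 9 rose, and 12 rose adjusted over the list alone (median 0.56, camera adjusted p = 2.80e-05, and adjusted p = 0.470 with an estimated correlation). The protease inhibitor Serpine2 rose from 3428 ± 470 to 6558 ± 1087 CPM (0.94 ± 0.15), the angiotensin receptor Agtr1a by 0.87 ± 0.14, desmin, Des, by 0.76 ± 0.14 and the mesangial transcription factor Gata3 by 0.72 ± 0.15. The podocyte list did not pass without atrasentan libraries 2 and 5 (-0.34, adjusted p = 0.0657), nor the endothelial list with the glomerular share as a covariate (0.20, adjusted p = 0.0688).

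Immune genes were higher with atrasentan. So were markers of red cells, which come with blood (4 of 6 rose, median 1.15, camera adjusted p = 0.0297, and adjusted p = 0.546 with an estimated correlation). Of 17 antigen presentation genes 16 rose, over all genes and adjusted over the list alone (median 1.71, camera adjusted p = 1.24e-16, and adjusted p = 0.336 with an estimated correlation). The class II gene H2-Aa rose by 2.35 ± 0.35, the class I light chain B2m by 1.73 ± 0.24, the class I heavy chain H2-D1 by 1.59 ± 0.22 and the peptide transporter subunit Tap2 by 1.33 ± 0.18 (edgeR adjusted p between 0.000149 and 0.000260). Of 28 interferon response genes 23 rose, with 24 adjusted over the list alone (median 1.06, camera adjusted p = 1.33e-10, and adjusted p = 0.470 with an estimated correlation), among them Tap1 (1.94 ± 0.37) and the immunoproteasome subunits Psmb9 (1.85 ± 0.31) and Psmb8 (1.63 ± 0.25). The interferon list mean was 4.83 and 4.65 log2 CPM in atrasentan libraries 4 and 5, below saline library 5 (4.91) and wild type library 1 (5.05). In the other atrasentan libraries it was 5.21 to 6.09. Of 20 macrophage genes 16 rose, with 17 adjusted over the list alone (median 1.12, camera adjusted p = 3.01e-07, and adjusted p = 0.470 with an estimated correlation). C1qa, C1qb and C1qc rose by 3.11 ± 0.63, 3.25 ± 0.61 and 3.23 ± 0.58, Aif1 by 2.87 ± 0.61 and the lysosomal protease Ctss by 1.74 ± 0.31. Of 18 lymphocyte genes 9 rose, with 9 adjusted over the list alone (median 0.89, camera adjusted p = 0.000664, and adjusted p = 0.545 with an estimated correlation), among them the immunoglobulin joining chain Jchain (1.35 ± 0.39, adjusted p = 0.0136). Complement genes split, with 12 rising and 4 falling of 24, and 13 and 5 adjusted over the list alone (median 0.69, camera adjusted p = 0.0654). The regulator Serping1 and the protease C1ra rose by 1.5 ± 0.23 and 1.35 ± 0.21, and C2 and C3 fell by 2.45 ± 0.39 and 2.36 ± 0.41. The complement list passed without saline library 3 or 5 (adjusted p = 0.0488 and 0.0494) or atrasentan library 2, 3, 5 or 7 (adjusted p = 0.0307, 0.0240, 0.0268 and 0.0315). It also passed with the glomerular share as a covariate (0.53, adjusted p = 0.0103), without atrasentan libraries 2 and 5 together (0.83, adjusted p = 0.0110) and without the low-count filter (0.46, adjusted p = 0.0385). With the glomerular share as a covariate the lymphocyte list did not pass (0.41, adjusted p = 0.273).

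Matrix, metabolic and immediate early genes also changed. Of 43 matrix genes 18 rose and 4 fell, with 20 and 4 adjusted over the list alone (median 0.39, camera adjusted p = 0.000165, and adjusted p = 0.5 with an estimated correlation). Col8a1 rose by 1.79 ± 0.19 (290 ± 66.4 against 83.9 ± 11.3 CPM, adjusted p = 6.44e-05), the proteoglycan Bgn by 0.96 ± 0.15, the matrix protease Mmp14 by 0.88 ± 0.15 and vimentin, Vim, by 0.86 ± 0.15. Of 28 fatty acid oxidation genes 20 fell and 1 rose, with 22 and 1 adjusted over the list alone (median -0.71, camera adjusted p = 2.25e-05, and adjusted p = 0.546 with an estimated correlation), among them Ppara (-3.12 ± 0.47) and the acyl-CoA dehydrogenase Acadm (-1.13 ± 0.22). That list did not pass with the glomerular share as a covariate (-0.12, adjusted p = 0.320). Of 28 glucose handling genes 14 fell and 2 rose, over all genes and adjusted over the list alone (median -0.43, camera adjusted p = 0.00907, and adjusted p = 0.583 with an estimated correlation), among them Slc2a2 (-3.72 ± 0.51). Of 20 immediate early and heat shock genes 13 fell and 1 rose, with 13 and 3 adjusted over the list alone (median -0.99, camera adjusted p = 2.55e-06, and adjusted p = 0.470 with an estimated correlation). The transcription factors Egr1 and Junb fell by 2.63 ± 0.38 and 1.80 ± 0.26 and the growth regulator Btg2 by 2.09 ± 0.28. The immediate early list was written as a technical one, and an effect of atrasentan and one of the preparation cannot be told apart here. In saline against wild type this list was higher, with none of the 20 called (median 0.49, camera adjusted p = 0.00098, and adjusted p = 0.543 with an estimated correlation), and it did not pass without wild type library 5 (0.36, adjusted p = 0.0517). With atrasentan against wild type 9 fell and 1 rose, with 10 and 1 adjusted over the list alone (median -0.50, camera adjusted p = 0.0230, and adjusted p = 0.840 with an estimated correlation). There it did not pass without wild type library 3 (-0.38, adjusted p = 0.0523) or 4 (-0.39, adjusted p = 0.0759), atrasentan library 2 (-0.45, adjusted p = 0.0631) or atrasentan libraries 2 and 5 together (-0.48, adjusted p = 0.125). Of 27 tubular injury genes 9 rose and 4 fell, with 9 and 5 adjusted over the list alone. There the median was 0.20 and the test direction up while the mean was -0.22 (camera adjusted p = 0.342), and osteopontin, Spp1, fell by 2.06 ± 0.49.

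The largest rises without overlap between the groups, beside C1qb, C1qc, C1qa and Aif1, were those of the protease inhibitor Serpina3f (3.90 ± 0.76, adjusted p = 0.00128) and the interferon-induced GTPase Gbp8 (2.73 ± 0.62). The largest falls, beside Slc5a12, were those of Cyp24a1, the vitamin D 24-hydroxylase (-5.09 ± 0.56, adjusted p = 7.13e-05), the phosphate transporter Slc34a3 (-3.99 ± 0.46), the lipid kinase Pik3c2g (-3.88 ± 0.49), the glucuronosyltransferase Ugt2b34 (-3.87 ± 0.58) and the transporter Slc16a14 (-3.86 ± 0.63).

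**Figure D3:**
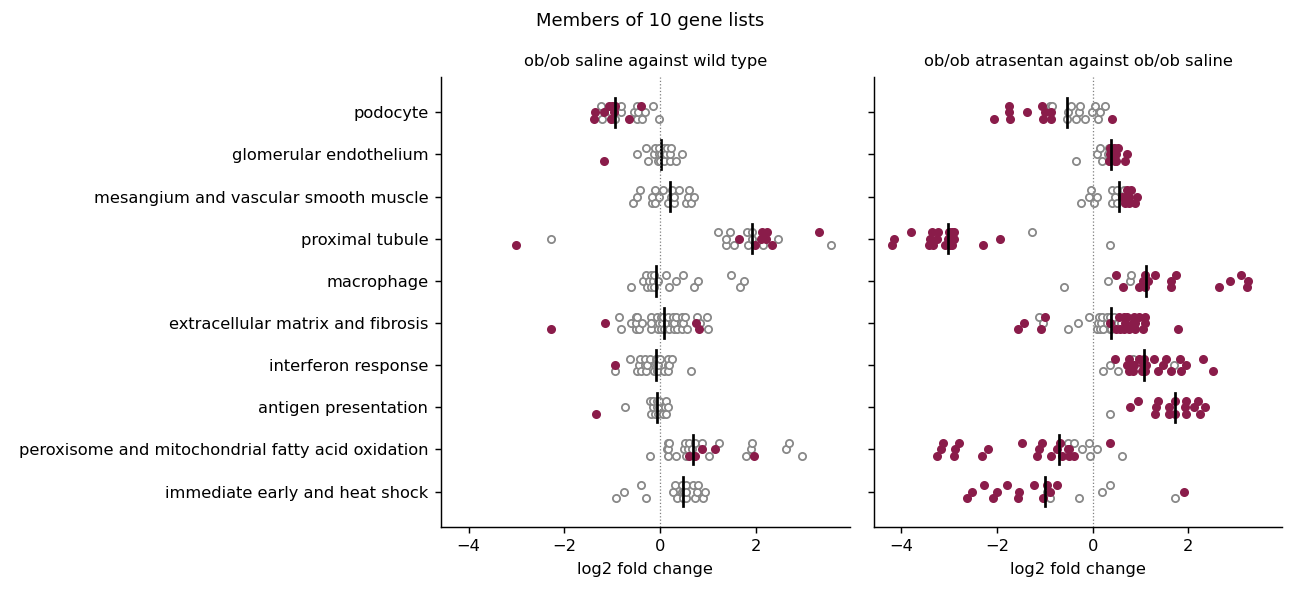
Log2 fold change of each tested gene of 10 lists for saline against wild type (left) and atrasentan against saline (right), with filled points for genes past an edgeR adjusted p of 0.05 and a bar at the list median. The proximal tubule median is 1.92 on the left and -3.02 on the right, and the antigen presentation median is -0.05 and 1.71.

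Of the 6001 genes, 2713 rose and 3288 fell, and 3840 changed by at least 1.5-fold. An unadjusted p under 0.05 was reached by 7973. The count was 41 with the proximal tubule mean as a covariate, 1094 with the glomerular share, 1931 with the share of reads outside genes and 2577 without saline libraries 1 and 3. It stayed between 4361 (without saline library 3) and 6338 (without atrasentan library 6) with 1 library left out. The proximal tubule mean (2.51 to 5.54 with atrasentan, 5.63 to 7.95 with saline) and the share of reads outside genes did not overlap between these groups, so as covariates they take up part of any difference between them. With the proximal tubule mean 72 of the 74 genes named here and called in this comparison lost the call, among them C1qb, whose log2 fold change went from 3.25 to 4.73 (adjusted p = 0.0750). The lost calls therefore do not tell genes of the tubule from others. Of the 74, 36 lost the call with the share of reads outside genes, 26 with the glomerular share, 12 without saline libraries 1 and 3 together, 2 without atrasentan libraries 2 and 5 together and 3 with some single library left out. Calb1 lost it without saline library 1 (-1.30, adjusted p = 0.0866) or 3 (-1.43, adjusted p = 0.0775), and Hba-a1, a hemoglobin gene that otherwise rose by 1.46 ± 0.45, without saline library 3 (1.26, adjusted p = 0.0537). Slc12a1 lost it without saline library 1 (-1.46, adjusted p = 0.0884) or 3 (-1.58, adjusted p = 0.0803) or atrasentan library 1 (-1.61, adjusted p = 0.0519) or 4 (-1.63, adjusted p = 0.0548).

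The gene named in the title, Clu (chromosome 14, 65968483 to 65981547, plus strand, GRCm38), was not called in any comparison. Its level was 176 ± 29.4 CPM in wild type (SD, n = 5), 274 ± 109 with saline (n = 5) and 186 ± 51.9 with atrasentan (n = 7). The log2 fold change was 0.64 ± 0.25 for saline against wild type (SE, edgeR adjusted p = 0.141), -0.56 ± 0.23 for atrasentan against saline (adjusted p = 0.0676) and 0.08 ± 0.23 for atrasentan against wild type (adjusted p = 0.831). The 5 saline libraries stood at 390, 182, 389, 171 and 238 CPM, and the highest were libraries 1 and 3, which also held the most proximal tubule RNA. The value for atrasentan against saline passed with DESeq2 (-0.58, adjusted p = 0.0496) and without saline library 2 (-0.67) or 4 (-0.69) or atrasentan library 6 (-0.65), and turned to 0.54 with the proximal tubule mean as a covariate and 0.24 with the glomerular share. That for atrasentan against wild type passed with the proximal tubule mean as a covariate (0.65, adjusted p = 0.0417). Without saline libraries 1 and 3 the value for atrasentan against saline was -0.08, and saline against wild type was 0.15. Within groups the log2 CPM of Clu and of the proximal tubule list went together over the 17 libraries (Pearson r = 0.742, permutation p = 0.00707, Spearman rho = 0.775, permutation p = 0.00318). This was the only relation of its kind computed, and r was 0.887 without atrasentan library 7 and saline library 3, the libraries farthest from the median.

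**Figure D4:**
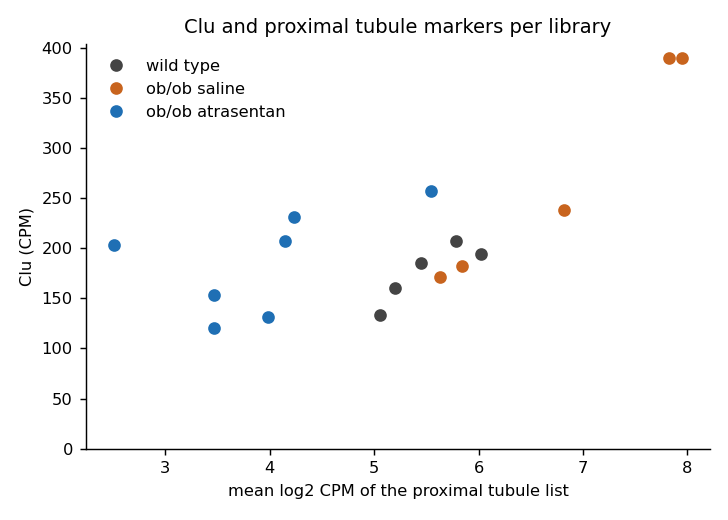
Clu in CPM against the mean log2 CPM of the proximal tubule list, 1 point per library, colored by group. The saline libraries with 390 and 389 CPM of Clu have the highest tubule means, 7.82 and 7.95.

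Genes of the endothelin system were examined because atrasentan blocks the receptor encoded by Ednra (chromosome 8, 77663031 to 77724464, minus strand). In saline-treated against wild type mice none of the 7 fixed endothelin genes that was tested was called by edgeR, DESeq2 or limma-voom. Edn1, which encodes the ligand endothelin-1 (chromosome 13, 42301476 to 42307990, plus strand), had a log2 fold change of 0.34 ± 0.16 (adjusted p = 0.222), Ednra of -0.01 ± 0.23 (adjusted p = 0.992) and Ednrb, the B receptor gene (chromosome 14, 103814625 to 103844402, minus strand), of -0.23 ± 0.36 (adjusted p = 0.778). With atrasentan against saline, Ednra rose from 34.1 ± 4.15 to 59.1 ± 18.6 CPM (0.79 ± 0.22, adjusted p = 0.0110) and Ece1, which cleaves the precursor of endothelin-1, rose by 0.49 ± 0.15 (adjusted p = 0.0162). Edn1 (0.36 ± 0.15, adjusted p = 0.0712) and Ednrb (0.08 ± 0.33, adjusted p = 0.878) were not called, and Edn1 passed without saline library 2 (0.49, adjusted p = 0.0166). The list of the endothelin system did not pass (median 0.08 and mean -0.36, test direction up, camera adjusted p = 0.868). Of all genes tested 33.8% were called in this comparison, so 2 calls among the 7 fixed endothelin genes do not stand out. The peptidase Mme, a neprilysin that also marks podocytes and proximal tubules, fell by 1.5 ± 0.28 (adjusted p = 0.000900). Both rises lost the call with each of the 3 covariates tried and without saline libraries 1 and 3. There the log2 fold changes lay between 0.39 and 0.80 for Ednra and between 0.39 and 0.62 for Ece1. Against wild type, atrasentan-treated mice had higher Ednra (0.79 ± 0.22, adjusted p = 0.0124), Ece1 (0.77 ± 0.15, adjusted p = 0.00100) and Edn1 (0.70 ± 0.15, adjusted p = 0.00226) and lower Mme (-2.26 ± 0.28). Ednrb was -0.15 ± 0.33 there (adjusted p = 0.764). As 29.2% of all genes tested were called against wild type, calls for Ednra, Ece1 and Edn1 among the 7 fixed genes do not stand out. These calls for Ednra, Ece1 and Edn1 were lost with the share of reads outside genes as a covariate (0.33, 0.91 and 1.06, adjusted p = 0.761, 0.164 and 0.0926), and that for Edn1 also with the proximal tubule mean (0.50, adjusted p = 0.0532).

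Genes that differed in saline-treated ob/ob mice were then compared with those that differed after atrasentan. Of the 910 genes of the disease comparison, 353 rose in disease and fell with atrasentan and 81 fell in disease and rose with atrasentan, 434 in all in opposite directions, and 47 rose in both and 41 fell in both. Independent lists of these sizes would share 105, 51.9, 87.0 and 62.9. Among the 434, 389 were not called against wild type, 32 lay past wild type on the other side and 13 were still called on the disease side. In comparison, 29.2% of all genes tested were called in atrasentan against wild type. That log2 fold change is the sum of the other 2 in the same fit. Genes picked for opposite calls therefore tend to lie near wild type by selection, and the 389 do not show a return to wild type. Opposite changes with the smallest p included the potassium channel Kcnk5 (2.16 ± 0.32, then -2.13 ± 0.29), Col27a1 (1.75 ± 0.31, then -1.57 ± 0.28), Nus1, a subunit of dolichol synthesis (1.27 ± 0.23, then -1.24 ± 0.21). Among falls in disease were Rasl12 (-1.09 ± 0.11, then 0.61 ± 0.10), Nrgn (-0.95 ± 0.16, then 1.14 ± 0.15) and Rab13, a GTPase of tight junction traffic (-0.68 ± 0.11, then 0.62 ± 0.10). Changes in the same direction included the vessel growth factors Angpt4 (1.65 ± 0.25, then 1.34 ± 0.23) and Vegfd (1.37 ± 0.24, then 1.30 ± 0.23), Tmem232 (1.60 ± 0.28, then 1.23 ± 0.25). Others were the ribonuclease Rnase4 (0.88 ± 0.14, then 0.91 ± 0.13), the G protein subunit Gnai1 (0.46 ± 0.08, then 0.49 ± 0.08) and the deubiquitinase Usp46 (-0.72 ± 0.12, then -0.57 ± 0.11). The edgeR adjusted p was at most 0.00791 for these 12 genes in both comparisons.

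The saline libraries enter both comparisons, which by itself gives opposite signs. The log2 fold changes had a correlation of -0.436 across genes, which are not independent replicates, and 20 simulations of unchanged groups that share the saline libraries gave -0.543 ± 0.011. The covariance was -0.244 against -0.0671 in the simulations, a difference of -0.177, and 61.5% of genes had opposite signs against 68.1% in the simulations. No simulation gave an opposite call. The simulations drew each gene on its own around 1 mean for all groups. They hold no variation in tissue makeup that moves many genes together. They therefore cannot show how many opposite calls such variation would give. In 20 splits of the saline libraries in which the comparisons shared no library, the median number of opposite calls was 14.5 (0 to 589), that of calls in the same direction was 15.5 (0 to 104), and the covariance was -0.192 (-0.252 to 0.0165). The count of 434 was 88, 105, 90, 226 and 56 without wild type library 1, 2, 3, 4 or 5, 52, 794, 48, 898 and 244 without saline library 1, 2, 3, 4 or 5, and 717 without atrasentan library 6. It was 1020 with DESeq2 and 194 with limma-voom, 9 without saline libraries 1 and 3, 1 with the glomerular share and 2 with the proximal tubule mean as a covariate, and 53 with the share of reads outside genes.

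Against wild type, atrasentan-treated ob/ob mice had lower podocyte markers and higher macrophage, antigen presentation and matrix genes. Of 25 podocyte genes 21 fell and 1 rose, over all genes and adjusted over the list alone (median -1.49, camera adjusted p = 7.37e-17, and adjusted p = 0.564 with an estimated correlation). Magi2 fell by 2.76 ± 0.26 (SE, 28.4 ± 10.4 CPM, n = 7, against 193 ± 50, n = 5), Plce1 and Lmx1b by 2.42 ± 0.25 and 2.42 ± 0.28 and nephrin, Nphs1, by 1.94 ± 0.23 (edgeR adjusted p between 3.74e-06 and 2.32e-05). Of 22 proximal tubule genes 11 fell and 1 rose, over all genes and adjusted over the list alone (median -1.25, camera adjusted p = 5.34e-05, and adjusted p = 0.660 with an estimated correlation). Of 20 endothelial genes 11 rose and 1 fell, with 15 and 1 adjusted over the list alone (median 0.40, camera adjusted p = 0.00169, and adjusted p = 0.592 with an estimated correlation). The receptor Eng rose by 0.87 ± 0.15 and Cldn5 fell by 1.51 ± 0.16. Of 20 mesangial genes 10 rose, with 13 adjusted over the list alone (median 0.58, camera adjusted p = 4.10e-06, and adjusted p = 0.564 with an estimated correlation), among them Serpine2 (1.34 ± 0.15) and smooth muscle actin, Acta2 (1.30 ± 0.31).

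Of 20 macrophage genes 13 rose, with 16 adjusted over the list alone (median 1.10, camera adjusted p = 7.13e-08), and C1qb, C1qa and C1qc rose by 4.92 ± 0.67, 4.87 ± 0.70 and 4.71 ± 0.63. Of 17 antigen presentation genes 15 rose and 1 fell, over all genes and adjusted over the list alone (median 1.57, camera adjusted p = 7.43e-12), with H2-Aa at 2.32 ± 0.35. Both lists had an adjusted p of 0.564 with an estimated correlation. Of 28 interferon response genes 17 rose, with 19 adjusted over the list alone (median 1.01, camera adjusted p = 6.87e-07, and adjusted p = 0.592 with an estimated correlation), among them Tap1 (1.87 ± 0.37). Of 43 matrix genes 22 rose and 6 fell, with 24 and 9 adjusted over the list alone (median 0.51, camera adjusted p = 8.70e-05, and adjusted p = 0.564 with an estimated correlation). Col8a1 rose by 2.61 ± 0.20 (290 ± 66.4 against 47.6 ± 12.2 CPM, adjusted p = 6.90e-07), Mmp2, a matrix protease, by 1.31 ± 0.18 and Bgn by 1.22 ± 0.15, and Col4a4, a collagen of the glomerular basement membrane made by podocytes, fell by 1.57 ± 0.22. Fibroblast genes went both ways, with 4 of 11 rising and 3 falling, over all genes and adjusted over the list alone (median 0.11 and mean -0.04, test direction up, camera adjusted p = 0.731), and here the proteoglycan Dcn rose by 2.0 ± 0.24 and Postn fell by 1.91 ± 0.27. None of 28 fatty acid oxidation genes was called by edgeR, over all genes or adjusted over the list alone (median -0.05, which was 0.03 without atrasentan libraries 2 and 5, camera adjusted p = 0.784).

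The largest rises without overlap between the groups, beside the C1q genes, were those of Qrfpr (4.94 ± 0.62), Gpr176, a receptor linked to the circadian clock (3.93 ± 0.42), and Serpina3f (3.89 ± 0.76). Their edgeR adjusted p lay between 1.16e-05 and 0.00115. The largest falls were those of Kap, an androgen-regulated protein of the proximal tubule (-4.27 ± 0.74), Luzp2 (-3.60 ± 0.51), Lctl (-3.42 ± 0.36), Astn2 (-3.08 ± 0.33), the angiotensin-cleaving aminopeptidase Enpep (-3.03 ± 0.47) and Mocs1, an enzyme of molybdenum cofactor synthesis (-2.98 ± 0.77). Over all genes 2619 rose and 2571 fell, which became 1897 and 3153 with upper-quartile scaling, and 7252 had an unadjusted p under 0.05. The count of 5190 was 582 with the share of reads outside genes as a covariate, 3369 with a minimum fold of 1.5, and between 4092 (without wild type library 3) and 5622 (without atrasentan library 5) with 1 library left out. No single library ended the call of any of the 42 genes named here and called in this comparison, and 23 lost it with the share of reads outside genes as a covariate.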

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

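In each group the highest and lowest library of 46 measures were set against the gap that chance exceeds in 1 of 20 groups, which was done in 138 groups, and 7 values lay beyond it where 6.9 are expected by chance. Wild type library 1 had 40965108 gene reads against 31849374 in the next of its group, and atrasentan library 5 had 52528747 against 41855297. In atrasentan library 7 the 10 most abundant genes took 6.37% of gene reads against 5.79% in the next. The mean log2 CPM of the macrophage list was 5.71 in atrasentan library 3 against 4.67 in the next, and that of the cell cycle list was 3.87 in the same library against 2.89. For the fatty acid oxidation list it was 5.85 in atrasentan library 6 against 4.90. The adrenal cortex list stood lowest in saline library 5, at -0.22 against 0.82 in the nearest other. No explanation was tested for these values.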

How the results depend on the processing

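The fits with the proximal tubule mean or the share of reads outside genes as a covariate, those without saline libraries 1 and 3 or atrasentan libraries 2 and 5, and the fit of the deposited normalized values were chosen after seeing the data. No paired analysis was possible because the labels number no replicates, and the sex covariate was not run. Over 230 single genes and lists, Clu not among them, 2490 values under the alternatives divided into 2048 with the same direction and side of the threshold, 389 that lost the call, 13 that gained one and 40 of the other sign. With 1 library left out these were 3689, 173, 27 and 21 of 3910. Lists were not counted in fits run without a list test, among them that with upper-quartile scaling. Except where named, the cause was not tested. The glomerular share is made from the podocyte and proximal tubule lists, so with it as a covariate those lists, and genes that go with them, move by construction. Lower numbers without libraries come in part from fewer mice.

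For saline against wild type the number of changed genes was 2003 with DESeq2, 550 with limma-voom and 1430 with only the 2 groups fitted. It was 6 with the glomerular share, 91 with the proximal tubule mean, 409 with the reads outside genes and 54 without saline libraries 1 and 3. For atrasentan against saline it was 3840 with a minimum fold of 1.5, and 1094, 41, 1931 and 2577 with the glomerular share, the proximal tubule mean, the reads outside genes and without saline libraries 1 and 3. For atrasentan against wild type it was 3369 with a minimum fold of 1.5 and 582 with the reads outside genes. The number of gene lists was 0 with an estimated correlation in each comparison and 0 with fry for saline against wild type. For atrasentan against saline it was 12 with the glomerular share and 13 without saline libraries 1 and 3. The number of endothelin genes fell to 0 with each covariate and without saline libraries 1 and 3 for atrasentan against saline, and to 0 with the reads outside genes against wild type. Opposite calls numbered 1020 with DESeq2, 194 with limma-voom, 1 with the glomerular share, 2 with the proximal tubule mean, 53 with the reads outside genes, 9 without saline libraries 1 and 3 and 14.5 (median) with the saline libraries split. With the endothelium list the share differed by -1.36 for saline and 1.92 for atrasentan against wild type.

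Clu for atrasentan against saline was -0.58 with DESeq2 (adjusted p = 0.0496, against 0.0496 to 0.815 over the alternatives other than leaving out 1 library, and as low as 0.0307 without saline library 4), 0.24 with the glomerular share and 0.54 with the proximal tubule mean. For saline against wild type it was -0.15 with the glomerular share. For atrasentan against wild type it was -0.0025 with upper-quartile scaling, 0.65 with the proximal tubule mean and -0.69 with the reads outside genes. For saline against wild type Ednra was 0.00046 with DESeq2, 0.0096 with limma-voom, 0.00044 with RLE scaling, 0.18 with the glomerular share and 0.011 in the deposited normalized table. Ednrb was 0.13 with the glomerular share, 0.041 with the proximal tubule mean and 0.21 without saline libraries 1 and 3. The endothelial list median was -0.0044 without the low-count filter. With the glomerular share the list medians were -0.058 for proximal tubule, -0.17 for distal tubule, -0.42 for collecting duct, -1.52 for loop of Henle, which then passed, -0.037 for fatty acid oxidation and 0.11 for interferon response. Without saline libraries 1 and 3 they were -0.49 for loop of Henle, 0.064 for macrophage and 0.072 for interferon response. The interferon list passed with a negative median without wild type library 2, 3 or 4 (camera adjusted p = 0.0425, 0.0119 and 0.0253). So it did without saline library 4 or 5 (0.0435 and 0.00520) and without the low-count filter (0.0476). Antigen presentation passed with a negative median without wild type library 2 or 3 (0.0389 and 0.0280) or saline library 1 or 5 (0.0254 and 0.0375).

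For atrasentan against saline the glomerular share gave list medians of 0.23 for distal tubule, 0.80 for collecting duct, 0.046 for loop of Henle and 0.17 for NRF2 targets, and values of -0.31 for Ednrb and 0.067 for Calb1. The proximal tubule mean gave -8.81e-05 for Edn1, -0.72 for Ednrb, 0.89 for Calb1, 0.017 for C3, -0.20 for Jchain, 0.85 for Slc12a1, 0.33 for Usp2, 0.87 for Spp1, 0.68 for Slc4a1 and 0.22 for Acadm. Arntl was 0.23 with the reads outside genes. Without saline libraries 1 and 3 the NRF2 list was at 0.014 and Ednrb at -0.37, and Ednrb was -0.070 without atrasentan libraries 2 and 5. Against wild type Ednrb was 0.92 with the reads outside genes, and the fatty acid oxidation list was 0.032 without atrasentan libraries 2 and 5.

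With 1 library left out, changed genes ranged from 216 to 1523 for saline against wild type, from 4361 to 6338 for atrasentan against saline and from 4092 to 5622 for atrasentan against wild type. In that order Clu ranged from 0.46 to 0.76, from -0.69 to -0.39 and from -0.016 to 0.16, the 7 fixed endothelin genes, which leave out Mme, gave 0 to 0, 2 to 3 and 3 to 3, lists 14 to 20, 17 to 23 and 14 to 17, and the glomerular share ranged from -2.55 to -1.80, from 1.86 to 2.61 and from -0.18 to 0.27. Opposite calls ranged from 48 to 898. For saline against wild type the list medians ranged from -0.071 to 0.087 for glomerular endothelium, from -0.00057 to 0.73 for loop of Henle, from -0.23 to 0.18 for macrophage and from -0.15 to 0.15 for antigen presentation, and Ednra from -0.11 to 0.14. Ednrb for atrasentan against saline ranged from -0.12 to 0.53. Against wild type the distal tubule list ranged from -0.078 to 0.52 and the lymphocyte list from -0.029 to 0.25. At these depths edgeR found 35.8% of genes changed 1.5-fold in simulated saline and wild type libraries, so smaller changes were often missed.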

Other observations

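Of the tests in this part, those of purer glomeruli and of genomic DNA against wild type were chosen only after the result was seen, genomic DNA and unspliced RNA were separated after the result on receptor genes was seen, and 1 more on the most abundant genes was run without a place among the explanations weighed. Some genes of the circadian clock differed between atrasentan-treated and wild type mice. Atrasentan-treated mice had lower Npas2 (-5.12 ± 0.89, SE, 0.222 ± 0.341 CPM, n = 7, against 7.66 ± 7.52, n = 5) and Arntl (-3.31 ± 0.53), which form the activating arm of the clock, and higher Cry1 (1.87 ± 0.33), a repressor in it (edgeR adjusted p = 0.000455, 0.000216 and 0.000518). Of 17 clock genes 2 rose and 3 fell there, near the share of all genes called in this comparison (29.2%). Adjusted over the list alone 4 rose and 3 fell. The median was 0.59 and the mean 0.06 (camera adjusted p = 0.0871), and the list passed without wild type library 1 (0.90, adjusted p = 0.0264) or 3 (0.81, adjusted p = 0.0218), without the low-count filter (0.58, adjusted p = 0.00562) and with fry (adjusted p = 0.0333). The calls of all 3 genes ended with the share of reads outside genes as a covariate (-4.30, -2.30 and 0.83, adjusted p = 0.187, 0.270 and 0.541). In saline against wild type only Arntl was called, and the call ended without wild type library 5 (adjusted p = 0.0585) or saline library 1 (adjusted p = 0.0525) or 3 (adjusted p = 0.0576), and 9 rose and 3 fell adjusted over the list alone (median 0.79, camera adjusted p = 0.0011, and adjusted p = 0.392 with an estimated correlation). In atrasentan against saline 2 fell, with 1 adjusted over the list alone (median -0.06, camera adjusted p = 0.745), among them the deubiquitinase Usp2 (-1.86 ± 0.48). The wild type libraries differed among themselves, with clock list means of 5.24, 5.03, 5.35, 4.37 and 4.10 log2 CPM in libraries 1 to 5. With atrasentan these means lay between 5.10 and 5.39. The time of day of killing is not given in the sources used here.

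Lists of inflammatory and cell cycle genes were higher with atrasentan by camera, but the cell cycle means of the libraries overlapped between the groups. Of 26 NF-kB targets and chemokines 10 rose and 1 fell against saline, with 11 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 0.000266, and adjusted p = 0.5 with an estimated correlation). Against wild type 14 rose and 1 fell, with 17 and 1 adjusted over the list alone (median 0.78, camera adjusted p = 1.31e-05, and adjusted p = 0.564 with an estimated correlation), among them the adhesion molecule Icam1 (1.33 ± 0.22) and the chemokine Cxcl16 (1.18 ± 0.17, edgeR adjusted p = 0.000127). In saline against wild type 2 rose, with 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.221), and the list passed without wild type library 1 (adjusted p = 0.0423) or saline library 1 (adjusted p = 0.0435) or 3 (adjusted p = 0.0332), without saline libraries 1 and 3 together (0.31, adjusted p = 0.000314) and with the glomerular share as a covariate (0.26, adjusted p = 0.000131). Of 25 cell cycle genes 8 rose against saline (median 0.67, camera adjusted p = 0.000108, and adjusted p = 0.546 with an estimated correlation) and 4 against wild type (median 0.53, camera adjusted p = 0.0122, and adjusted p = 0.840 with an estimated correlation), with 8 and 4 adjusted over the list alone, among them the replication factor Mcm5 (0.73 ± 0.15 against saline). The cell cycle list mean was 3.87 log2 CPM in atrasentan library 3. In the other atrasentan libraries it was 2.39 to 2.89, within the range of the wild type libraries. The highest saline library stood at 2.78. Among the 17766 genes tested 2713 rose against saline and 2619 against wild type. The 4 of 25 cell cycle genes that rose against wild type therefore do not stand out. Of 6 red cell genes 4 rose against saline, with 5 adjusted over the list alone (median 1.15, camera adjusted p = 0.0297, and adjusted p = 0.546 with an estimated correlation). Of 27 tubular injury genes 10 rose with atrasentan against wild type, over all genes and adjusted over the list alone (median 0.50, camera adjusted p = 0.0211, and adjusted p = 0.564 with an estimated correlation), among them lipocalin 2, Lcn2 (2.80 ± 0.71), and ceruloplasmin, Cp (1.49 ± 0.22). That list was also higher in saline against wild type, where 1 rose, with 6 rising and 1 falling adjusted over the list alone (median 0.45, camera adjusted p = 0.0245, and adjusted p = 0.392 with an estimated correlation).

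Of 25 vascular tone genes 9 rose and 5 fell with atrasentan against saline, with 10 and 5 adjusted over the list alone, and the median of 0.18 stood against a mean of -0.02 (camera adjusted p = 0.124). The nitric oxide regulator Ddah1 and the growth factor Vegfa fell by 2.11 ± 0.29 and 0.89 ± 0.20, and Npr3, a clearance receptor of natriuretic peptides, rose by 0.74 ± 0.15 (edgeR adjusted p = 0.000192, 0.00288 and 0.00133). Of 26 sodium and water transport genes 6 fell, with 5 adjusted over the list alone (median -0.72, camera adjusted p = 0.0149, and adjusted p = 0.597 with an estimated correlation). Of 38 oxidative phosphorylation genes 11 fell, with 10 adjusted over the list alone (median -0.35, camera adjusted p = 0.00303, and adjusted p = 0.650 with an estimated correlation). Of 7 mitochondrially encoded genes 3 fell, with 7 adjusted over the list alone (median -0.71, camera adjusted p = 0.0203, and adjusted p = 0.566 with an estimated correlation). These last 3 lists had medians of 0.82, 0.35 and 0.72 in saline against wild type, and the proximal tubule list moved the same way in both comparisons. Lists that did not pass in atrasentan against saline, each with its median and camera adjusted p, were lipid and sterol synthesis (-0.12, 0.373), endoplasmic reticulum stress (0.15, 0.181), cytosolic ribosomal proteins (median 0.14 and mean -0.00, 0.416), fibroblast (0.36, 0.0879), adipocyte (-2.11, 0.157), renin-angiotensin (-0.97, 0.150), NRF2 targets (-0.28, 0.195, but -0.36, 0.0328 without saline library 4) and adrenal cortex (median -0.05 and mean 0.11, 0.945).

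Each count of changed genes was set against other splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included. Fitted on the libraries of the 2 groups alone, the real splits called 1430 genes for saline against wild type, 4925 for atrasentan against saline and 4398 for atrasentan against wild type, and the highest of the other splits called 0, 2424 and 2140. In each comparison only 1 of the 100 splits, the real one, gave as many genes. The possible splits numbered 126 for saline against wild type and 792 for each atrasentan comparison. Most of the 792 were not fitted, so chance is an unlikely source of these counts but is not excluded. The splits do not separate the treatment from other differences between the groups, such as tissue makeup or the order of the libraries.

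The atrasentan libraries had fewer genes detected and fewer reads outside genes, and a difference in depth was excluded, since after thinning every library to the lowest total the lowest saline library still had 1424 more genes than the highest atrasentan library, and 1363 more without the 10 most abundant genes of each library. Less genomic DNA was excluded as the whole cause of the difference from saline, since reads on 1426 olfactory and vomeronasal receptor genes overlapped between atrasentan (48.1 ± 7.66 CPM, here and below without TMM scaling) and saline (46.6 ± 10.3 CPM, lowest saline minus highest atrasentan -25.6). Against wild type it stays open, since these reads were fewer with atrasentan than in wild type (76.4 ± 16.8 CPM) but the libraries overlapped (lowest wild type minus highest atrasentan -10.0). Less unspliced RNA stays open and is a candidate explanation, since reads on 1822 genes of the annotation class TEC that lie within protein-coding genes were lower in every atrasentan library (334 ± 161 CPM) than in every saline library (900 ± 138 CPM), by 9.20 CPM at the closest. Whether such a difference came from the treatment or from the preparation cannot be told apart, because the library numbers follow the groups.

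In the atrasentan libraries proximal tubule and podocyte markers were lower than with saline and macrophage markers higher. Bias by GC content or transcript length was excluded, since each list median lay at least 0.555 beyond the central 95% of 10000 matched random lists. The higher endothelial and mesangial lists (medians 0.37 and 0.56) are what purer glomeruli predict. The lower podocyte list is not (mean per library 6.59 with atrasentan against 7.31, difference -0.724, exact permutation p = 0.0341), and 20 of its 25 members were lower. Its median of -0.546 was smaller than the interquartile range of its members (0.883), but that range is a spread between genes and not between mice. Without atrasentan libraries 2 and 5 the podocyte list did not pass (camera adjusted p = 0.0657), though its median stayed negative (-0.34). Purer glomeruli do not predict a lower podocyte list, and they stay open for the proximal tubule, endothelial and mesangial lists. The choice of TMM over RLE or upper-quartile scaling was excluded as the source, since each median kept its sign and a size of at least 0.554 with these. An error shared by all these scalings was not tested. An effect of atrasentan on these cells stays open and was not tested.

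Clu was higher with saline than in wild type and lower with atrasentan than with saline, though neither passed, and the tubule content of the libraries may carry this. Only the proximal tubule list was set against Clu, so it cannot be told apart from later tubule segments. The distal tubule mean was also highest in saline libraries 1 and 3 (6.97 and 6.95). Atrasentan library 7 had the lowest proximal tubule mean (2.51) but 203 CPM of Clu. With the proximal tubule mean as a covariate, 0.168 of the difference from wild type was left (0.64 ± 0.25 to 0.11 ± 0.21, SE, edgeR adjusted p = 0.947), while that between atrasentan and saline went past 0 (-0.56 ± 0.23 to 0.54 ± 0.31, adjusted p = 0.416). The first value is what tubule content predicts. The second did not pass, and the tubule means of these groups did not overlap (2.51 to 5.54 with atrasentan, 5.63 to 7.95 with saline). The covariate therefore takes up part of any difference between them. The second value cannot decide, so this could not be settled. More Clu RNA in the tubules of diabetic mice stays open as well, since tubule content differs between the groups and the cells were not measured apart.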
